A study of Lactiplantibacillus plantarum with 5 samples.

How the data were processed

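Each of the 5 arrays carried RNA of 2 time points of the same retentostat fermentation, labelled with Cy3 and Cy5, and the labels name the time point of each dye. The authors' scanner output consists of ImaGene combined files, per the file headers, with channel 1 from the Cyanine 3 scan and channel 2 from the Cyanine 5 scan. These files give spot and local background intensity as raw linear values, per the file headers and the values, with no normalization, for 15744 spots per array, 536 of them controls. The authors' value table of the same arrays holds log2 ratios. It was made with limma, per the submitters' processing notes, and its other steps and its direction are not given in the sources used here. Set against the scanner values, its columns correlated with loess-normalized log2 ratios of Cy5 over Cy3 without background correction at r = -0.9998 to -0.99999, with slopes of -1.001 to -0.9995, so it holds log2 of Cy3 over Cy5. Its column medians lay at -0.0017 for day 3 against day 0, 0.0035 for day 31 against day 0, 0.0020 for day 17 against day 3, 0.0026 for day 0 against day 17 and 0.0018 for day 31 against day 17. Without background correction its ratios are compressed, with slopes of -0.58 to -0.51 against the corrected ratios used here.

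The spot quality marks deposited by the authors were used as follows. A spot marked empty in a channel, which in these files means a signal within 2 background SD of the background, was taken as not above background. Flag 3, which marks other spot failures, stood on 22.1% of gene spots on the array of day 3 against day 0 and on 25.0% on that of day 31 against day 17, and on 1.98% to 2.65% on the other 3. Such spots were kept, and leaving them out was an alternative. Median spot signals were 616 to 719 against median local backgrounds of 501 to 519, and 47.2% to 62.4% of gene spots per array were above background in at least 1 channel. Median pixel signals reached the scanner's limit on at most 6 gene spots of an array. Photomultiplier settings were 60 or 65 for Cy3 and 55 or 60 for Cy5. Over probes spotted in duplicate, the SD of a spot's log2 ratio was 0.16 to 0.20.

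From the spot means and background medians, intensities were corrected with normexp (offset 50) and normalized by loess within each array in limma 3.58.1 under R 4.3.3, with control spots at weight 0. Log2 ratios of Cy5 over Cy3 were averaged over the spots of a probe and then over the probes of a locus. Of 9170 probes, 6309 were kept, those above background in at least 1 channel of at least 2 arrays, and 648 of 3092 loci had no such probe. One linear model with 3 coefficients, for days 3, 17 and 31 relative to day 0, was fitted to the 5 arrays with lmFit, and all 6 comparisons of time points were taken from it with contrasts.fit and eBayes. Benjamini-Hochberg adjustment was made within each comparison. Every SE and p covers technical error only, and the model had no dye term. Day 31 was labelled with Cy5 on both its arrays. A gene-wise dye bias therefore fell partly in the residual and also shifted the day 31 ratios, which their SE does not cover. With a dye effect in the model, lp_0409 at day 17 against day 0 stayed at -6.37. In the same fit lp_0129 at day 31 against day 0 went from 5.45 to 5.60. The prior had 5.73 degrees of freedom. Where a gene was above background on no array of the dimmer day, its change is given as a bound, from levels per channel after loess and Aquantile normalization, with the dim level set at the higher of the gene's own level and the lowest probe above background. Where the fold under any setting with background correction, the direct array alone included, was lower still, the lowest of them is printed as the bound, a choice made after the data were seen. Such bounds hold on the background-corrected scale only, are open to dye bias and make no allowance for SE. For lp_2312 the gene's own day 3 level was the one used, so its lowest value is printed as an estimate and not as a bound.

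Data for day 31 against day 0 were simulated over 2444 genes, in a single draw per setting. In each, 100 genes changed by log2 1 and 100 by log2 2, up or down. With no simulated dye bias, 100% of both sizes were recovered and 2.44% of calls were false. With a simulated gene-wise dye bias of SD 0.15, 96% and 100% were recovered and 7.11% of calls were false. With a dye effect in the model, which leaves 1 residual degree of freedom, 5.24% of calls were false without the simulated bias and 9.09% with it. In the data for this comparison 1396 genes were called, and 553 of them had an absolute log2 ratio of at least 1. Smaller changes were not simulated, and far fewer genes changed than were called. The noise was drawn with the fitted spread, which already held any real dye bias. The recovery and false shares therefore do not carry over to the reported calls.

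The rule for named genes was set before the data were examined. It takes the largest rises and falls among called genes whose directly hybridised array has the sign of the fit and whose probes all share that sign. For day 31 against day 3, which had no direct array, the condition on the probes alone was applied. It had a limit to genes with a known name or product, which could not be applied, because the files do not pair IDs with names and the reference table, of another strain, matched 0 IDs. For the same reason it was limited to 2 loci each way per comparison, and the single control genes it names are not reported. Of 32 gene lists set in advance, 31 need gene names and were not tested here. The list of plasmid-borne genes was filled from the marks p1, p2 and p3 in the IDs, a reading that the files do not spell out. It was tested with camera at a correlation of 0.01, and its p is adjusted over the 6 comparisons, since it was the only list within each. Camera with an estimated correlation also rests on the 2 residual degrees of freedom. A call lost there does not show that correlation between genes was the cause. For the p3 genes at day 3 against day 0, the estimated correlation was 0.0010, under the preset value. Their camera p still went from 0.00077 to 0.061. It was also set against 10000 random lists matched on mean intensity. No other column of the files holds values of samples left unmapped. The arrays' positions and photomultiplier settings were the only batch-like entries in the headers, and no slide was shared in a way the files record.

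The planned design assumed another scanner software, whose own log ratio is not part of these files. Alternatives were no background correction, median centring, the authors' value table, a dye effect, looser and stricter filters on dim probes, the median over probes, an intensity trend with a robust prior, a further limit of 1 on the absolute log2 ratio, each array left out in turn, and the direct array alone. Median pixel signals, leaving out flag 3 spots, the p3 and tRNA groups, the random lists and the runs of neighbouring loci were added after the data were seen.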

Results

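RNA of Lactiplantibacillus plantarum WCFS1, a lactic acid bacterium, was compared on 5 two-colour DNA microarrays over 4 time points of 1 anaerobic retentostat culture. A retentostat is a continuous culture in which a filter holds back the cells while medium flows through, so that a constant glucose supply is shared by ever more cells and growth slows towards 0. The labels give the specific growth rate as 0.0250 per h at the start (day 0), 0.0074 per h at day 3, 0.0009 per h at day 17 and 0.0002 per h at day 31. The arrays formed a loop. Day 3 and day 31 were each hybridised directly against day 0, day 17 against day 3, day 0 against day 17, and day 31 against day 17. Day 0 and day 17 were therefore each measured on 3 arrays, and day 3 and day 31 on 2 arrays each. Of 3092 loci with probes, 2444 were tested, each as the mean of 1 to 3 probes.

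The design text states that all samples came from the same fermentation, so no time point had a biological replicate. The 5 arrays left 2 residual degrees of freedom, which hold technical error alone. This is hybridisation error and part of any dye bias of a gene, for which the model has no term. Day 31 was labelled with Cy5 on both its arrays, so such a bias also shifts every ratio of day 31, beyond its SE. With a dye effect in the model, the median over all genes for day 31 against day 17 went from 0.020 to 0.041. For comparisons among days 0, 3 and 17 this median stayed the same. Every adjusted p from limma given here compares RNA samples and not growth conditions, and the small number of arrays limits the precision. A change is called where the Benjamini-Hochberg adjusted p lay under 0.05. All log2 ratios are of the later over the earlier day, taken from the Cy3 and Cy5 labels of each array. The authors' value table runs the opposite way, as log2 of Cy3 over Cy5, without stating a direction, so all directions given here rest on the dye labels. The files identify genes by locus IDs and do not pair these with gene names, and 0 of the 3092 IDs matched the reference table. All ranks of named loci are those of the fitted, background-corrected ratios. For each comparison, up to 2 IDs that rose and 2 that fell are therefore named, by ID only. IDs that carry the mark p1, p2 or p3 (43 tested of 44 on the array) were read as the genes of the 3 plasmids of this strain and formed the list of plasmid-borne genes. A loop in which every ratio was exact would sum to 0. Over the 2444 genes, the sums had an SD of 0.51 on the log2 scale for the loop through days 0, 3 and 17, and of 0.27 for the loop through days 0, 31 and 17. The SD of the log2 ratios themselves over genes was 0.39 for day 3 against day 0 and 1.06 for day 31 against day 0. A loop sum adds the errors of 3 arrays, and in the first loop their dye bias too, so its SD is not the error of a fitted ratio. The median SE of a fitted ratio was 0.14 in both of these comparisons. The size of all ratios rests on the background correction: among the genes called for day 31 against day 0, the median absolute log2 ratio was 0.83, and 0.41 without it.

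The comparison of day 3 with day 0 asked what changed in the first days after cell retention began, while growth slowed from 0.0250 to 0.0074 per h. The locus lp_3286 rose by the most among those that met the rule for named genes, with a log2 ratio of 2.65 ± 0.26 (SE; limma adjusted p = 0.0013), and it was 3.46 without the array of day 3 against day 0. It was followed by lp_3662 at 1.76 ± 0.20 (adjusted p = 0.0026). The adjacent locus numbers lp_2701 and lp_2700 had the lowest fitted ratios by the rule. Both were above background on all 3 arrays of day 0 and on 0 of the 2 arrays of day 3, so their falls are given as bounds on the background-corrected scale, at least 4.21-fold for lp_2701 and at least 4.52-fold for lp_2700 (adjusted p = 0.00026 for both). Without background correction their log2 ratios were -0.77 and -0.81, and their rank was not kept: lp_0412 then stood at -1.44 and lp_0409 at -1.28. Of the 43 plasmid-borne genes, 3 rose and 0 fell, or 1 and 0 adjusted over the list alone, and their median log2 ratio was 0.25, or 0.087 without background correction. The list stood above other genes with the preset correlation (limma camera adjusted p = 0.00013 over the 6 comparisons). This was lost with an estimated correlation, which also rests on 2 residual degrees of freedom (camera p = 0.079 with an estimated correlation). It was lost too under the strict filter on dim probes, where the median was 0.17. The list's median lay above those of all 10000 random lists matched on intensity, the highest of which reached 0.24. These lists were drawn gene by gene, while neighbouring chromosomal loci correlated at r = 0.43 in this comparison. Medians of lists of neighbouring genes may therefore spread more widely than theirs. In total 98 genes rose and 124 fell, 11 and 42 of them by at least 2-fold. The count depended strongly on the processing: it fell to 114 without background correction, to 113 from the authors' value table and to 25 with only the 1347 genes whose probes were above background everywhere, and rose to 1043 with a gene-wise dye effect, to 760 without the array of day 17 against day 3, and to 407 without that of day 3 against day 0. With either of these arrays left out, day 3 rested on 1 array and its spread was taken from the other days. The fit with a dye effect left 1 residual degree of freedom. Its p values were too small for a spread estimated per gene (limma adjusted p = 2.1e-72 for lp_0047 between days 17 and 31). The counts of that fit, in every comparison, thus rest on a spread largely common to all genes. They are not evidence of further changes. With median centring in place of loess, 34 genes rose and 83 fell.

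The comparison of day 17 with day 0 covered the slowing of growth to 0.0009 per h. The neighbouring locus numbers lp_2313 and lp_2312 rose the most among the genes that met the rule, with log2 ratios of 5.48 ± 0.15 (limma adjusted p = 1.9e-07) and 5.38 ± 0.11 (adjusted p = 9.9e-08). At day 0, lp_2313 was above background on 1 of 3 arrays and lp_2312 on 2 of 3, and at day 3 they were above it on 1 of 2 and 0 of 2, so their levels before day 17 were at or near the limit of measurement. Without background correction their log2 ratios were 3.37 and 3.44. The largest falls were those of lp_0410 at -6.69 ± 0.32 (adjusted p = 1.9e-06; -5.88 without the array of day 0 against day 17) and of lp_0409 at -6.37 ± 0.18 (adjusted p = 1.9e-07), and both remained above background on all 3 arrays of day 17. Of the 43 plasmid-borne genes, 42 rose and 0 fell (42 and 1 adjusted over the list alone), with a median log2 ratio of 1.47, or 2.77-fold, and 0.69 without background correction. All 38 genes marked p3 rose, by log2 ratios of 0.55 to 3.99, and so did both genes marked p1 and 2 of the 3 marked p2. Of the genes outside the list, 29.0% rose. The list's shift held with the preset correlation (limma camera adjusted p = 1.4e-15) and with an estimated correlation (p = 0.020 with an estimated correlation). In total 738 genes rose and 672 fell, 281 and 186 of them by at least 2-fold. The count was 676 of 1347 genes when probes had to be above background in both channels of all arrays.

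**Figure D1:**
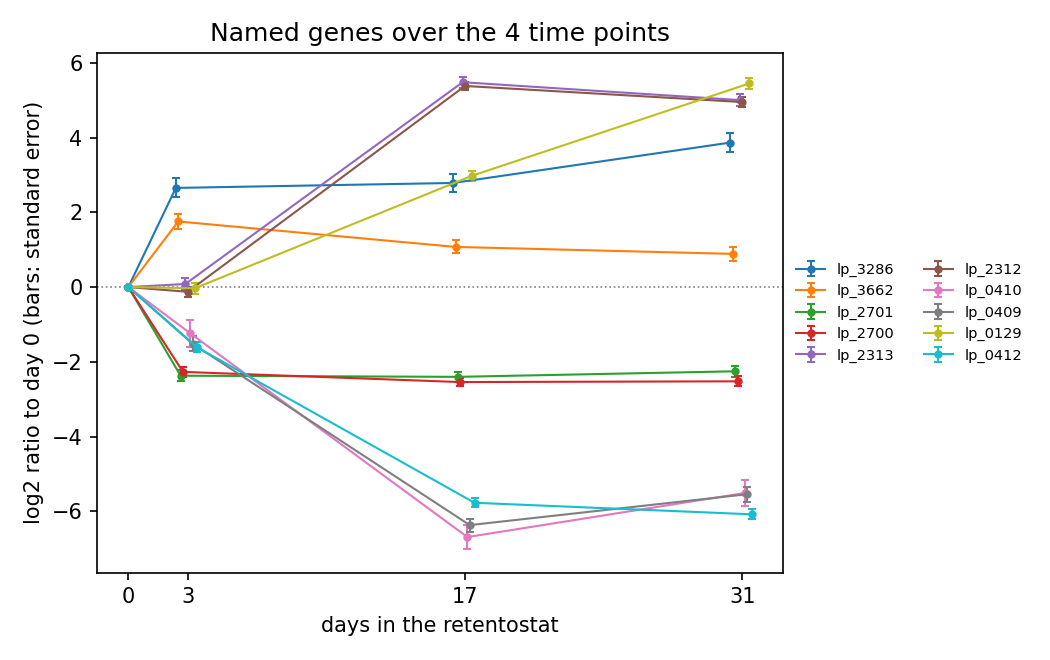
Log2 ratio to day 0 (vertical axis) against days in the retentostat (horizontal axis) for the 10 loci named in the comparisons with day 0; points are fitted values from the 5 arrays, bars their standard errors, and points after day 0 are shifted sideways slightly for legibility. The loci lp_2312 and lp_2313 lay above 4.9 at days 17 and 31; their earlier values, those of lp_2700 and lp_2701 after day 0 and those of lp_0412 at days 17 and 31 come from signals at or near background and show no exact level.

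The comparison of day 31 with day 0 set the slowest growth, 0.0002 per h, against the start. The locus lp_0129 rose the most, with a log2 ratio of 5.45 ± 0.14 (limma adjusted p = 2.9e-07). It had reached 2.98 ± 0.13 at day 17 and stood at -0.03 ± 0.14 at day 3. The locus lp_2313 had a fitted log2 ratio of 5.00 ± 0.17 (adjusted p = 3.7e-07) against a day 0 level above background on 1 of 3 arrays, and of 2.93 without background correction. The lowest fitted ratios were those of lp_0412 at -6.08 ± 0.14 (adjusted p = 2.9e-07), which was above background on 1 of the 2 arrays of day 31, and of lp_0409 at -5.55 ± 0.20 (adjusted p = 4.3e-07). Without background correction their order turned, with -3.95 for lp_0412 and -4.45 for lp_0409, and lp_0410 lay below both at -4.76. Of the 43 plasmid-borne genes, 42 rose and 0 fell, with the same numbers adjusted over the list alone, and their median log2 ratio was 1.61, or 3.05-fold, and 0.75 without background correction. All 38 genes marked p3 rose, with a median of 1.61 and a range of 0.50 to 4.53. The 1 list member that was not called, a gene marked p2, had a log2 ratio of -0.18. The list's shift held with the preset correlation (limma camera adjusted p = 1.7e-15) and with an estimated correlation (p = 0.020 with an estimated correlation). In total 736 genes rose and 660 fell, 344 and 209 of them by at least 2-fold. Comparing day 31 with day 0, 173 genes were above background on both arrays of day 31 and on 0 of 3 of day 0, 134 of which were called higher, against 29 genes with the reverse pattern, 28 of which were called lower. The corresponding numbers were 50 and 46 at day 17, and 15 and 37 at day 3. Spots in general were also above background more often in the day 31 channels (55.0% and 58.5%) than in the day 0 channels (42.6% to 49.3%). Day 31 was labelled with Cy5 on both its arrays and day 0 with Cy3 on 2 of 3, and the Cy5 channel had the larger share above background on 4 of the 5 arrays. These numbers are therefore open to dye and array differences, and the days have unequal numbers of arrays. The count of 1396 changed genes fell to 708 without the array of day 31 against day 0, to 908 without that of day 31 against day 17 (day 31 then rested on 1 array, with its spread taken from the other days), and to 666 of the 1347 genes under the strict filter on dim probes.

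**Figure D2:**
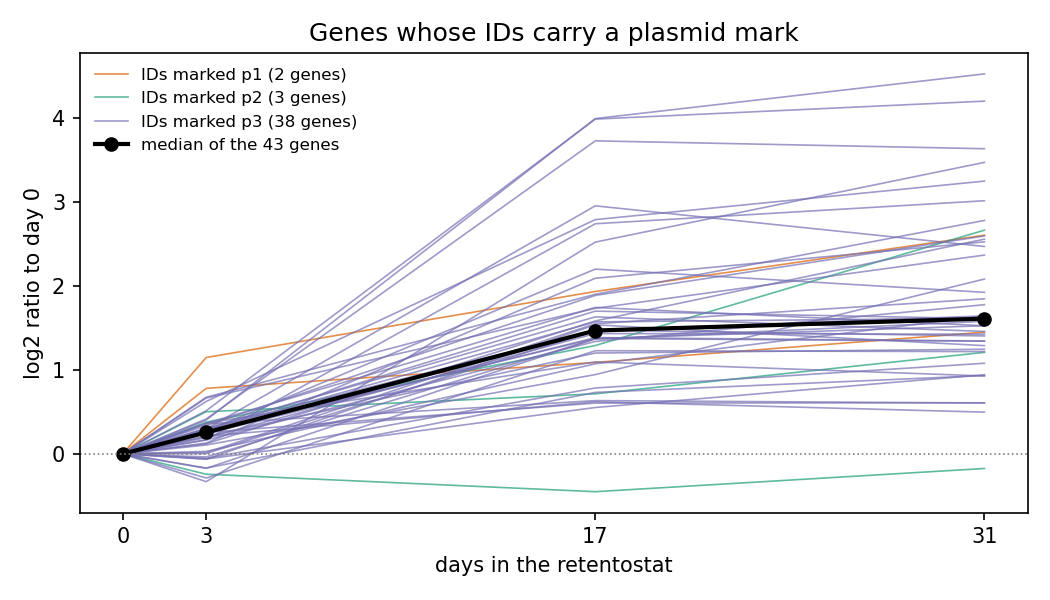
Log2 ratio to day 0 (vertical axis) against days in the retentostat (horizontal axis) for the 43 genes whose IDs carry a plasmid mark; each thin line is a gene, coloured by its mark, and the black line is the median. The median was 0.25 at day 3, 1.47 at day 17 and 1.61 at day 31, and 1 gene marked p2 lay below 0 throughout.

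Of the successive intervals, the one from day 3 to day 17 had the most called genes, 1012, against 222 before and 311 after it. In that interval lp_2312 rose 44.3-fold on the lowest of its background-corrected estimates (limma adjusted p = 3.9e-07). It was above background on 0 of the 2 arrays of day 3, so this fold gives no exact size and is not a bound. Its log2 ratio was 3.39 without background correction. The locus lp_2313 rose by a log2 ratio of 5.40 ± 0.17 (adjusted p = 7.4e-07), from a level above background on 1 of the 2 arrays. The loci lp_0410 and lp_0409 fell by log2 ratios of -5.46 ± 0.36 (adjusted p = 2.4e-05; -6.33 without the array of day 17 against day 3) and -4.86 ± 0.20 (adjusted p = 2.5e-06). Of the 43 plasmid-borne genes 37 rose and 0 fell (39 and 0 adjusted over the list alone), with a median of 1.24, or 0.59 without background correction (limma camera adjusted p = 2.7e-16; p = 0.018 with an estimated correlation). In total 552 genes rose and 460 fell. The count of 1012 became 1531 with a gene-wise dye effect and 452 under the strict filter.

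Between day 17 and day 31, lp_0129 rose by a further log2 ratio of 2.47 ± 0.14 (limma adjusted p = 0.00041). The locus lp_0047 rose at least 4.44-fold on the background-corrected scale (adjusted p = 0.00041), being above background on both arrays of day 31 and on 0 of the 3 of day 17, and its log2 ratio was 0.97 without that correction. The largest falls by the rule were those of lp_1568a, with a log2 ratio of -1.65 ± 0.37 (adjusted p = 0.025), and of lp_0512 at -1.39 ± 0.15 (adjusted p = 0.0016). The call for lp_1568a was lost under 4 alternatives, with an adjusted p of up to 0.11, and its log2 ratio was -2.36 with a gene-wise dye effect. Of the 43 plasmid-borne genes 7 rose and 1 fell, the same as adjusted over the list alone, with a median of 0.21, or 0.13 without background correction (limma camera adjusted p = 0.0093). This shift was lost with an estimated correlation on 2 residual degrees of freedom (camera p = 0.15 with an estimated correlation). It was lost too without the array of day 31 against day 17. In total 229 genes rose and 82 fell. Without the array of day 31 against day 17 the count of 311 fell to 48, without that of day 31 against day 0 it was 170, without either array that carried day 3 it was 742, with a gene-wise dye effect 937, with median centring 195, and under the strict filter 67.

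Day 31 and day 3 were never on one array, so their comparison ran through days 0 and 17. The locus lp_0129 was higher at day 31 by a log2 ratio of 5.48 ± 0.18, and lp_2312 by 31.0-fold on the lowest of its background-corrected estimates (limma adjusted p = 2.5e-06 for both). At day 3 lp_2312 was above background on 0 of 2 arrays, so its fold gives no exact size and is not a bound. Its log2 ratio was 2.90 without background correction. The locus lp_0412, above background on 1 of the 2 arrays of day 31, was lower by -4.47 ± 0.17 (adjusted p = 2.5e-06; -2.51 without background correction) and lp_3170 by -4.31 ± 0.66 (adjusted p = 0.0016), the latter with the largest standard error of the named loci. The value of lp_3170 was -3.23 without the array of day 3 against day 0, -5.38 without that of day 17 against day 3, and -5.26 with a gene-wise dye effect. Its mean log2 levels per channel were 12.6 at day 31 and 15.2 at day 3, closer together than the fitted ratio states, so its size is uncertain. Of the 43 plasmid-borne genes 36 were higher and 0 lower (37 and 0 adjusted over the list alone), with a median of 1.51, or 0.68 without background correction (limma camera adjusted p = 6.4e-16; p = 0.019 with an estimated correlation). In total 537 genes were higher and 390 lower. The count of 927 was 555 without the array of day 31 against day 0, 486 without that of day 31 against day 17, 385 under the strict filter and 1442 with a gene-wise dye effect.

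**Figure D3:**
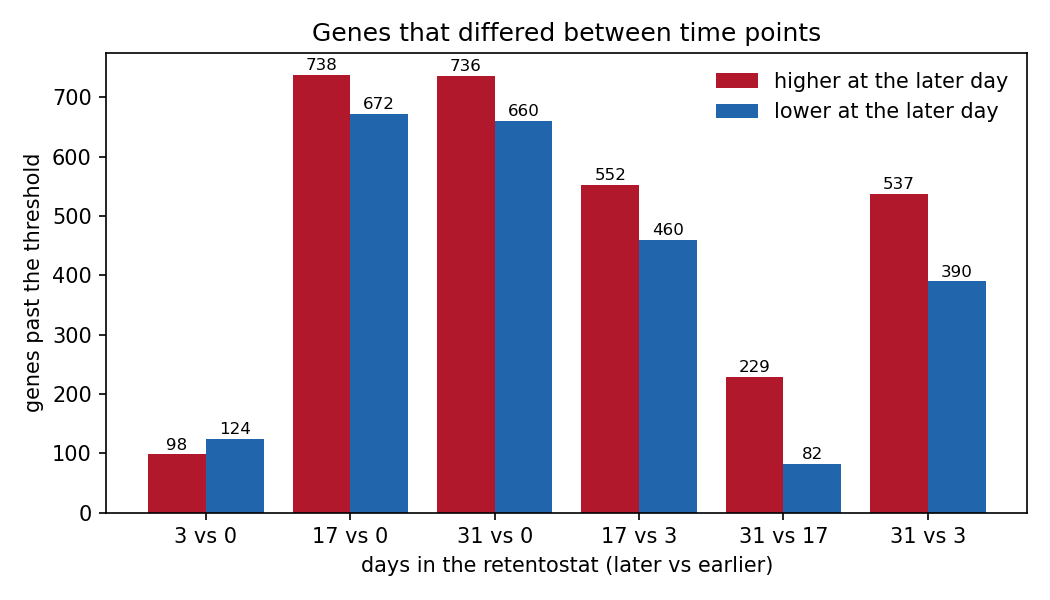
Number of genes with an adjusted p under 0.05 (vertical axis) in each of the 6 comparisons of days in the retentostat (horizontal axis), higher and lower at the later day; 2444 genes were tested in each. The comparisons of day 17 and day 31 with day 0 gave 738 and 736 higher and 672 and 660 lower genes, against 98 and 124 for day 3 with day 0.

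The changes at day 17 and day 31 largely concerned the same genes. Of the 736 genes higher at day 31 than at day 0, 594 were also higher at day 17 and 69 at day 3, and their median log2 ratio went from 0.17 at day 3 to 0.73 at day 17 and 0.94 at day 31. Of the 660 lower genes, 529 were lower at day 17 and 112 at day 3, with medians of -0.23, -0.65 and -0.75. Independent lists of these sizes would share 222 higher and 181 lower genes between days 17 and 31. Across genes, which are not independent replicates, the log2 ratios of days 17 and 31 to day 0 correlated with a Pearson r of 0.93 and a Spearman rho of 0.90. Both comparisons use the day 0 RNA and overlapping arrays, and simulated arrays with no change gave an r of 0.44. The covariance was 0.933, against 0.0093 in the simulation. Day 0 was a single RNA sample and could not be split, so that part of the overlap that comes from this sample was not measured. The 2 arrays that shared no RNA, day 3 over day 0 and day 31 over day 17, had a Pearson r of -0.13 and a Spearman rho of -0.14 across genes. Both carried the later day in Cy5, so a gene-wise dye bias would add its variance to their covariance. That variance was put at 0.023 from the loop sums, and the covariance was -0.024.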

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

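The comparison of these probes with the negative controls was chosen after the data were seen. Of the probe classes outside the gene table, those with mtf in their ID gave signals. Of the 150 spot measurements of probes with mtf in their ID (30 spots on each of 5 arrays), 65.3% were above background in at least 1 channel, with 53.3% to 76.7% on single arrays. Of the 150 measurements of their counterparts marked as reverse, 43.3% were above background, with 26.7% to 63.3% on single arrays. Negative control spots (77 on each array) were above background in 0 of 385 measurements, and gene spots in 54.7%. If all measurements were independent, 0 of 385 would allow a share of up to 0.779%. Probes marked antisense and SRP (5 spots each on each array) were above background in 0 of 25 measurements each, and spike-in probes in 0 of 1000. On the same terms, 0 of 25 would allow a share of up to 12%. All arrays measured the same spots, so the true limits are wider. The files do not say what mtf stands for, and no explanation was tested.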

How the results depend on the processing

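Median pixel signals and leaving out flag 3 spots were chosen after the data were seen. Of 96 recomputed counts of changed genes, 66 stayed within 1.5 times the reported count. For day 3 against day 0 the count was 222, and became 53 with a further limit of 1 on the absolute log2 ratio, 1043 with a gene-wise dye effect, 117 with median centring, 114 without background correction, 113 from the authors' value table and 25 under the strict filter on dim probes. Median centring changed its split from 98 higher and 124 lower to 34 and 83. With the limit on the log2 ratio the counts were 467 for day 17 against day 0, 553 for day 31 against day 0, 284 for day 17 against day 3, 75 for day 31 against day 17 and 434 for day 31 against day 3. Under the strict filter they were 676, 666, 452, 67 and 385 in that order, with 1347 genes tested in place of 2444. With a dye effect they were 1531 for day 17 against day 3, 937 for day 31 against day 17 and 1442 for day 31 against day 3. These counts and the 1043 above rest on a spread largely common to all genes. Median centring gave 195 for day 31 against day 17. With 1 array left out in turn, which leaves 1 residual degree of freedom, and for day 3 or day 31 a single array whose spread is taken from the other days, counts ran from 177 to 760 for day 3 against day 0, 1042 to 1655 for day 17 against day 0, 708 to 1711 for day 31 against day 0, 800 to 1200 for day 17 against day 3, 48 to 742 for day 31 against day 17 and 486 to 1226 for day 31 against day 3. The lowest for day 31 against day 17 came without its own array. Without an array that carried day 3, the residual came only from the loop whose sums had an SD of 0.27. Without an array of day 31, it came only from the loop with an SD of 0.51. How far this accounts for the counts was not tested. Apart from this and the limits on log2 ratio and genes tested, the cause was not tested. No gene was called in the direction opposite to the reported call under any of these settings. The median of the plasmid-borne genes kept its sign in all 90 recomputations and its call in 88, but not its size: without background correction it was 0.087, 0.69 and 0.75 for days 3, 17 and 31 against day 0, and 0.69 and 0.75 from the authors' value table at days 17 and 31. For day 3 against day 0 the call was lost under the strict filter, at a median of 0.17. For day 31 against day 17 it was lost without the direct array, at 0.19, within a range of 0.19 to 0.28 over the arrays left out. With an estimated correlation, which also brings in the 2 residual degrees of freedom, camera lost the call in the same comparisons, at p = 0.079 and p = 0.15. Of 389 recomputed values of named loci, 377 kept direction and call, or moved by less than 1 SE on the direct array. Of the rest, 8 moved by more there, and lp_1568a lost its call in 4. Not all of the 389, nor all 90 plasmid-borne medians, were free to change. The limit on the log2 ratio left all 24 of its values of named loci as they were. A trend with a robust prior left every ratio and list median as it was. A dye effect left all ratios among days 0, 3 and 17 unchanged. These shares thus overstate stability. In size, 46 of the 389 lay over 1.5 times from the reported fold. Of these, 19 of 24 came without background correction and 19 of 24 from the authors' value table, all smaller (lp_2701 went from -2.37 to -0.77, lp_2700 from -2.27 to -0.81 and lp_0047 from 2.43 to 0.97 without correction), 5 with an array left out, 2 with a dye effect and 1 on the direct array. Between-array Aquantile normalization leaves each ratio as it is and was not counted. The scanner's own log ratio and a slide block were not run, since these files hold neither. Each array paired 2 time points and the fit used these ratios within arrays, so no separate paired analysis was run. Spot signals only modestly above background limit the values of dim genes, whose ratios are drawn towards 0.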

Other observations

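The tests on runs of neighbouring loci against shuffled orders, on the tRNA group and on the loop sums were chosen after the results were seen. Changed genes were grouped along the chromosome. With the 2394 tested chromosomal loci in the order of their locus numbers, 381 of the 1351 changed at day 31 against day 0 lay in 49 runs of at least 5 consecutive loci called in the same direction, 177 of them higher and 204 lower. The longest falling run, from lp_0394 to lp_0422, held 22 tested loci with a median log2 ratio of -2.15 at day 31, -2.23 at day 17 and -0.93 at day 3, and 12 of the 22 were already lower at day 3. It holds the 3 loci from lp_0409 to lp_0412 named in the comparisons with day 0. The longest rising run, from lp_0635 to lp_0656, held 21 loci with medians of 0.24 at day 3, 1.64 at day 17 and 2.55 at day 31. At day 17 against day 0, 390 genes lay in such runs, and at day 3 against day 0, 36.

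Of the 14 IDs marked tRNA, 5 were tested. Their median log2 ratio between day 17 and day 31 was -0.74, below those of all 10000 random lists matched on intensity, the lowest of which reached -0.56. Of these 5, 1 was called lower and 0 higher. The shift passed with the preset correlation (limma camera adjusted p = 0.010). It was lost with an estimated correlation, of 0.50, on 2 residual degrees of freedom (camera p = 0.21 with an estimated correlation). It did not pass in the other 5 comparisons, with limma camera adjusted p from 0.064 to 0.94. At day 31 against day 0, where it did not pass (adjusted p = 0.24), their median was -0.61, with 2 called lower.

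The runs of changed genes were weighed against 3 technical explanations. Chance order is argued against, since 381 genes lay in runs and the highest of 10000 shuffled orders gave 86. A gene-wise dye bias is argued against as well: with a dye effect in the model 491 genes lay in runs, above the highest of its shuffled orders at 189. The calls of that fit rest on a spread largely common to all genes. A dye effect leaves the ratios of day 17 to day 0 unchanged. There 390 genes lay in runs in the fit without it, and the highest shuffled order gave 97. Spots of neighbouring loci in a run were 67.9 spots apart on average. The central 90% of the mean distances over 1000 random draws ran from 67.4 to 69.3, which argues against position on the array. Genes next to each other in bacteria are often transcribed together, which may be the source of the runs; strand and transcription units were not used here, so this hypothesis was not tested.

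The rise of the genes marked p3 at day 31 was weighed in the same way. Background correction and loess are argued against as its source, since the median of the 38 genes was 0.76 with uncorrected signals and 1.59 with median centring. A gene-wise dye bias is argued against, since the median was 1.55 with a dye effect in the model. A single factor for the whole replicon, as more copies per cell would give, predicts members that move alike within array error. Over the 27 members above background on all arrays of both days, the log2 ratios ran from 0.93 to 4.53. Their SD of 0.94 was 6.70 times their median SE of 0.14, more than array error alone gives. That SE leaves out dye bias at day 31, put at an SD of 0.15 from the loop sums, and any compression of ratios that differs between probes. At day 17 a dye effect leaves the ratios to day 0 unchanged. There the 38 genes had an SD of 0.88 against a median SE of 0.13. The spread argues against a single factor acting alone on these members, unless compression differed widely between probes, which was not measured. All 27 rose by at least 0.93, so a shared factor with further changes of single genes may still contribute. DNA left in the RNA, which would add to signals and not multiply them, was not tested and stays open. The slower growth itself stays open and untested, since 1 culture gave all samples.

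The sums of log2 ratios around the 2 closed loops differed in spread, with SDs of 0.51 and 0.27, and correlated across genes at r = 0.62. The first loop passes through 3 arrays in the same dye order and the second does not. A larger error on 1 array is argued against, since the covariance of the sums exceeded the variance of the second by 0.0119 (bootstrap over genes 0.0039 to 0.020). A gene-wise dye bias is consistent with the values: the covariance was 1.01 times (bootstrap 0.94 to 1.07) the value that the variances fix under it. Under that hypothesis the dye bias had an SD of 0.15 and the array error an SD of 0.13 on the log2 scale. The fit with a dye effect called 443 genes for it, on a spread largely common to all genes. Such a bias would also shift the day 31 ratios, whose median SE against day 0 was 0.14.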
